A study of Homo sapiens with 18 samples.

How the data were processed

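Messenger RNA levels were measured in 3 human gastric cancer cell lines, NUGC4, MKN1 and AZ521, each with and without a combination of 2 bacterial lipopeptide mimics. Pam3Cys-Ser-(Lys)4 is a triacylated lipopeptide that acts on TLR2 with TLR1, and FSL-1 is a diacylated lipopeptide that acts on TLR2 with TLR6. Per the labels, cells in 24-well plates were kept without serum for 24 h and then given 10 µg of the ligands, a dose the series text gives per ml, and RNA was taken at 6 h. The controls carry a saline label in the sample characteristics and are called untreated in the titles, and they are called untreated here. The labels also state that the lines were authenticated by short tandem repeat profiling. The 18 Affymetrix U133 Plus 2 arrays form 6 groups, each line with and without ligands, of 3 arrays each. Nothing in the labels says whether the numbered wells of a group were separate cultures on separate days.

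The deposited values are log2 expression values, made by the authors with RMA in the affy package under R 2.12.0, per the submitters' processing notes. RMA corrects for background, normalizes the arrays by quantiles and summarises the probes of each probe set on the log2 scale. Whether all 18 arrays were normalized together, and whether probe sets were filtered, is not stated. The table held 41006 probe sets on 18 arrays, with values from 1.24 to 13.86 and array medians within 0.06 of each other. No 2 arrays were identical, and 0 arrays were left out.

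The platform annotation paired 33710 of the probe sets with a gene, 32292 with 1 gene symbol and 1418 with several. The other 7296, of which 45 are control probe sets, had no gene symbol there. Symbols were updated through Entrez identifiers to the RefSeq gene table, and 35 symbols without a match kept the annotated name. Probe sets with several symbols were not used to name genes. For each of the 16861 genes, the probe set with the highest mean over the 18 arrays was kept. The 11422 genes with a log2 value of at least 5 on at least 3 arrays were tested, and 5439 dimmer genes were not.

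Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited log2 values. A model of the 6 group means was fitted to all 18 arrays, so that the groups shared 1 estimate of the spread with 12 residual degrees of freedom. The contrasts were ligand minus untreated in each line, the differences of these responses between lines, and the differences between the untreated lines. P-values were adjusted by the Benjamini-Hochberg method over the 11422 genes, and the threshold was an adjusted p under 0.05. These p-values measure only the spread between the arrays at hand. A rank or permutation test of 3 arrays against 3 cannot give a two-sided p under 0.1, and the number of arrays limits the precision of every value. Errors of changes are standard errors from limma, and errors of levels are standard deviations over 3 arrays.

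Gene lists were written before the data were examined. The 24 lists hold 343 genes, of which 305 were measured and 254 tested. Of these, 17 concern the response (TLR2 receptor complex, MyD88 signalling, NF-kB feedback, chemokines, cytokines, EGFR ligands, apoptosis inhibitors, immediate early genes, type I interferon response, antigen presentation, acute phase and epithelial defence, matrix and adhesion, cell cycle, cholesterol synthesis, unfolded protein and integrated stress response, hypoxia and glycolysis, and housekeeping). The others hold markers of gastric, intestinal, epithelial and mesenchymal identity and of leukocytes, fibroblasts and endothelium. The 15 response lists with at least 4 tested genes were tested with camera at its preset correlation of 0.01, adjusted over all lists and the 3 lines. Camera compares the genes of a list with all other tested genes, so a list can be called while its median change lies near 0. List genes without a probe set of their own in the annotation used here were not analysed here.

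The genes named were also chosen by a rule set before the data were examined. For each line the rule took up to 10 rises and 10 falls, the largest among genes past the threshold whose 3 ligand arrays lay all above or all below the 3 untreated arrays. It added the receptor genes and early adaptors, up to 4 members of each list past the threshold, the 10 largest response differences between each pair of lines, and the identity lists in untreated cells. Where no member of a list passed, up to 2 were given as values. CLDN7 in AZ521 was added outside the rule.

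The replicate numbers were checked for pairing before blocked fits were compared. Over the tested genes, deviations from the group mean of same-numbered ligand and untreated arrays correlated at 0.27, 0.28 and 0.25 in NUGC4 and at 0.14, 0.26 and 0.30 in AZ521. These numbers were therefore treated as pairs in the blocked fits and the regroupings, from the data and not from the labels. The main counts, errors and p-values come from the fit without a block. Where a fit with the number as a block changed a call, it is given beside the result or with the alternatives at the end.

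The method was tested on simulated data, with known changes put into seeded sets of the 11422 genes. Each gene had 1 spread, estimated from the real arrays and shared by all groups, and the arrays were drawn independently. Of genes changed by 0.5 on the log2 scale, 71% were recovered in NUGC4, 77% in MKN1 and 80% in AZ521. Of genes changed by 1, 98%, 98% and 99% were recovered, and 11, 7 and 15 genes without a change were called. For response differences of 0.5 the shares were 40.2%, 47.5% and 51.8% for NUGC4 minus MKN1, NUGC4 minus AZ521 and MKN1 minus AZ521, and for differences of 1 they were 92.9%, 92.7% and 93.4%, with 16, 28 and 22 false calls. A list shifted by 0.5 in simulated NUGC4 arrays was called, and 0 of the 44 other list tests were. The simulated noise was independent between genes, whereas the genes of the real lists had estimated correlations of up to 0.642. The simulation therefore does not give the rate of false list calls in the real data. Equal spread in the lines and unpaired replicates were built into the simulation. The recovered shares therefore cannot test whether the real arrays meet these assumptions.

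Alternatives covered 2 further scalings, the filter on dim genes, the probe set per gene, the variance model, the arrays in the fit, the replicate number as a fixed or random block, stricter thresholds, other list tests, and leaving out each array. Centring on the tested genes and a covariate for the GAPDH 3' minus 5' probe set difference were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.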

Results

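The series measured messenger RNA levels in NUGC4, MKN1 and AZ521 gastric cancer cells 6 h after a combination of TLR2 ligands or saline, with 3 arrays in each of the 6 groups. The first principal component, with 57.4% of the variance, set AZ521 apart from the other lines, and the second, with 38.6%, set MKN1 apart. The third, with 2.4%, separated the ligand and untreated arrays of NUGC4. On it the arrays of MKN1 and AZ521 also parted by treatment, over shorter distances and in AZ521 in the opposite order. The medians of the 18 arrays lay within 0.06 of each other on the log2 scale.

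Before any ligand, the lines differed in epithelial identity. AZ521 had low values of most genes that mark epithelial cells: EPCAM, an epithelial adhesion protein, had a log2 value of 2.69 ± 0.21 (SD, n = 3), against 12.42 ± 0.10 in NUGC4 and 11.97 ± 0.10 in MKN1. CDH1, which encodes E-cadherin, was at 2.24 ± 0.46 in AZ521 and at 11.46 ± 0.07 and 11.21 ± 0.08 in the other lines. AZ521 instead had high levels of VIM, the mesenchymal filament vimentin, at 12.72 ± 0.09, and of ZEB1, a repressor of epithelial genes, at 9.35 ± 0.03. NUGC4 held VIM at 4.37 ± 0.16 and MKN1 at 4.42 ± 0.26.

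Of 12 epithelial genes tested, 12 were higher in NUGC4 than in AZ521 and 11 were higher in MKN1, with median differences over all 12 of 6.16 and 6.36. Of 6 mesenchymal genes tested, 4 were lower in NUGC4 and 4 were lower in MKN1 than in AZ521, and 1 was higher in each. The exceptions were TWIST1, a mesenchymal transcription factor at 5.47 ± 0.03 in NUGC4 and 2.26 ± 0.12 in AZ521, and SNAI1, another, at 5.10 ± 0.12 in MKN1 and 4.16 ± 0.14 in AZ521. Among 5 fibroblast genes, 4 were higher in AZ521 than in either other line, among them COL3A1, a fibrillar collagen, and DCN, the matrix proteoglycan decorin, at 9.43 ± 0.30. COL1A1, another fibrillar collagen, went the other way, with 3.26 ± 0.31 in AZ521 and 8.58 ± 0.23 in MKN1.

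The epithelial lines carried different gastrointestinal genes. Of 8 intestinal genes tested, 5 were higher and 3 lower in NUGC4 than in MKN1. LGALS4, an intestinal lectin, was at 12.37 ± 0.06 in NUGC4 and 4.22 ± 0.09 in MKN1, and VIL1, which encodes the brush border protein villin, was at 9.53 ± 0.30 and 3.31 ± 0.10. Of 10 gastric genes, 3 were higher and 5 lower in NUGC4 than in MKN1. CLDN18, a tight junction claudin, was at 11.75 ± 0.19 in NUGC4 and 2.63 ± 0.19 in MKN1, whereas TFF1, a secreted gastric trefoil peptide, was at 7.64 ± 0.23 and 11.59 ± 0.17. LYZ, the lysozyme gene in the leukocyte list, was at 12.51 ± 0.09 in NUGC4 and 2.33 ± 0.03 in MKN1. The leukocyte genes CD3E, CD163 and ITGAM and the endothelial genes PECAM1, CDH5, VWF and KDR had log2 values below 5 in the untreated groups.

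The receptor was weakly expressed. TLR2 was at 5.15 ± 0.23 in NUGC4, 4.31 ± 0.09 in MKN1 and 4.14 ± 0.09 in AZ521, and NUGC4 exceeded the others by 0.84 ± 0.12 (SE) and 1.01 ± 0.12. Its partners TLR1 and TLR6 and the co-receptors CD14 and CD36 had values below 5 in every group and were not tested. MYD88, the adaptor shared by most Toll-like receptors, was at 9.86 ± 0.12 in NUGC4, 9.31 ± 0.03 in MKN1 and 5.89 ± 0.28 in AZ521.

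**Figure D1:**
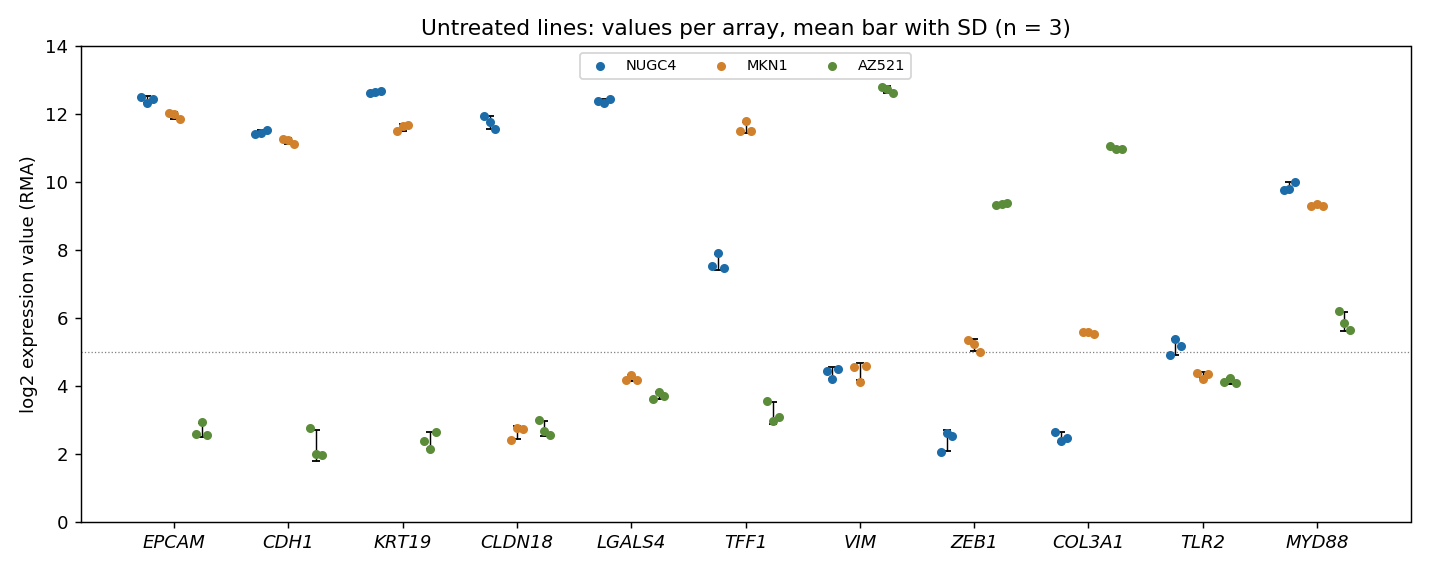
Log2 expression values of identity and receptor genes on the 3 untreated arrays of each line, with bars for the SD; the dotted line marks the log2 value of 5 used as the filter. EPCAM, CDH1 and KRT19 lay above 11 in NUGC4 and MKN1 and below 3 in AZ521, and VIM showed the opposite order.

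In limma, 9058 of 11422 genes differed between untreated NUGC4 and MKN1, 9529 between NUGC4 and AZ521, and 9195 between MKN1 and AZ521 (adjusted p under 0.05). The hybridisation spike-in bioB differed between the lines and had a mean of 7.77 in NUGC4, 7.57 in MKN1 and 5.34 in AZ521, while bioC was at 9.28, 9.10 and 9.32. Values between 2 and 4 lie near background, so differences that start there are imprecise.

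In NUGC4 the ligands raised chemokine messages by the largest median among the fixed lists. CXCL1 rose by 7.79 ± 0.13 on the log2 scale (SE, n = 3 per group), CXCL2 by 7.73 ± 0.19 and CXCL8 by 7.04 ± 0.24, and CXCL6 by 7.82 ± 0.10 from near background, which makes its size imprecise; these chemokines draw neutrophils. CCL20, which draws lymphocytes and dendritic cells with the receptor CCR6, rose by 6.69 ± 0.22 to a log2 value of 13.30 ± 0.07. Other large rises were those of SERPINB7, a protease inhibitor, by 5.76 ± 0.12, and PTGS2, the inducible cyclooxygenase that starts prostaglandin synthesis, by 5.57 ± 0.17. COXFA4L3 rose by 6.17 ± 0.45.

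Of 13 chemokine genes tested, 13 rose, with a median change of 6.32. The NF-kB feedback list, which holds inhibitors and subunits that NF-kB itself induces, had 11 of 13 genes rising. TNFAIP3, which encodes the inhibitor A20, rose by 3.13 ± 0.21, NFKBIA, which encodes the inhibitor IkB-alpha, by 2.04 ± 0.16 and NFKBIZ by 1.90 ± 0.11. Of 12 cytokine genes 8 rose, among them IL23A, a subunit of interleukin 23, by 4.42 ± 0.15, TNFSF15 by 3.70 ± 0.17 and TNF by 2.35 ± 0.15. Among 13 apoptosis inhibitors 8 rose and 2 fell, with BCL2A1 up by 3.84 ± 0.18 and CFLAR, which blocks caspase 8, up by 2.29 ± 0.08. BCL2A1 started at 1.88 ± 0.15, near background.

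Epithelial defence genes rose in NUGC4 as well, 10 of 10 tested. They included PI3, the protease inhibitor elafin, by 4.66 ± 0.15, PIGR, which carries immunoglobulin A across epithelium, by 4.35 ± 0.24, and DUOX2, a peroxide-producing oxidase, by 3.53 ± 0.16. Of 13 matrix and adhesion genes 9 rose and 1 fell, with ICAM1, a ligand for leukocyte integrins, up by 4.13 ± 0.16 and MMP7, a matrix protease, up by 2.36 ± 0.15. Of 22 type I interferon response genes 14 rose and 0 fell, including the transcription factor IRF1 by 2.22 ± 0.10, OAS3, an antiviral enzyme, by 2.20 ± 0.12 and IFIH1, an RNA sensor, by 2.10 ± 0.17. Of 13 antigen presentation genes 9 rose, such as the immunoproteasome subunit PSMB9 by 1.79 ± 0.24 and the peptide transporter subunits TAP2 by 1.74 ± 0.11 and TAP1 by 1.23 ± 0.11.

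TLR2 rose in NUGC4 by 0.63 ± 0.12, and MYD88 had a change of 0.17 ± 0.14 that did not pass. Of 13 MyD88 signalling genes 5 rose and 2 fell, and IRAK2, a kinase of the receptor complex, rose by 2.32 ± 0.09 and CHUK, a subunit of the IkB kinase, by 0.52 ± 0.11. Of 3 EGFR ligand genes 2 rose, HBEGF by 0.92 ± 0.16 and TGFA by 0.56 ± 0.11. Of 19 immediate early genes 10 rose and 1 fell, with DUSP5 and DUSP6, phosphatases that act on the kinase ERK, up by 2.05 ± 0.14 and 1.29 ± 0.19. The immediate early list was called up with the preset correlation but not with an estimated one (adjusted p = 0.136 with an estimated correlation).

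Metabolic and growth genes moved in mixed directions. Of 10 cholesterol synthesis genes 5 rose and 1 fell, with HMGCS1, an early enzyme of the pathway, up by 0.90 ± 0.15; this list's call was lost too (adjusted p = 0.385 with an estimated correlation). Among 26 cell cycle genes 5 fell and 0 rose, CCNB2, a mitotic cyclin, by 0.75 ± 0.13 and TYMS, an enzyme of thymidylate synthesis, by 0.50 ± 0.12. The cell cycle list did not pass (adjusted p = 0.361), but it was called down with the replicate number as a block (adjusted p = 0.0426, with a range of 0.0117 to 0.934 over 19 alternatives), and 2 rather than 5 genes passed when adjusted over the list alone. Of 11 stress response genes 4 rose and 4 fell, of 13 hypoxia and glycolysis genes 5 rose and 2 fell, and neither list passed (adjusted p = 0.363 and 0.0988). Of 8 housekeeping genes 1 passed, SDHA, with a rise of 0.32 ± 0.06.

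Genes with large falls in NUGC4 were AQP11, a water channel, which fell by 2.58 ± 0.15, TP53INP1, a p53 target, which fell by 2.54 ± 0.16, and CYS1, a cilium protein, which fell by 2.37 ± 0.23. CYP1B1, a cytochrome P450, fell by 2.27 ± 0.25, and BBS12, a gene of the ciliopathy Bardet-Biedl syndrome, fell by 1.97 ± 0.11. Among identity genes, whose lists were not tested as sets, 2 of 12 epithelial genes fell, 2 of 6 mesenchymal genes rose and 1 fell, 2 of 10 gastric genes rose, and 2 of 8 intestinal genes rose and 2 fell; of the marker genes of other cell types, 1 of 2 leukocyte and 1 of 5 fibroblast genes rose.

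**Figure D2:**
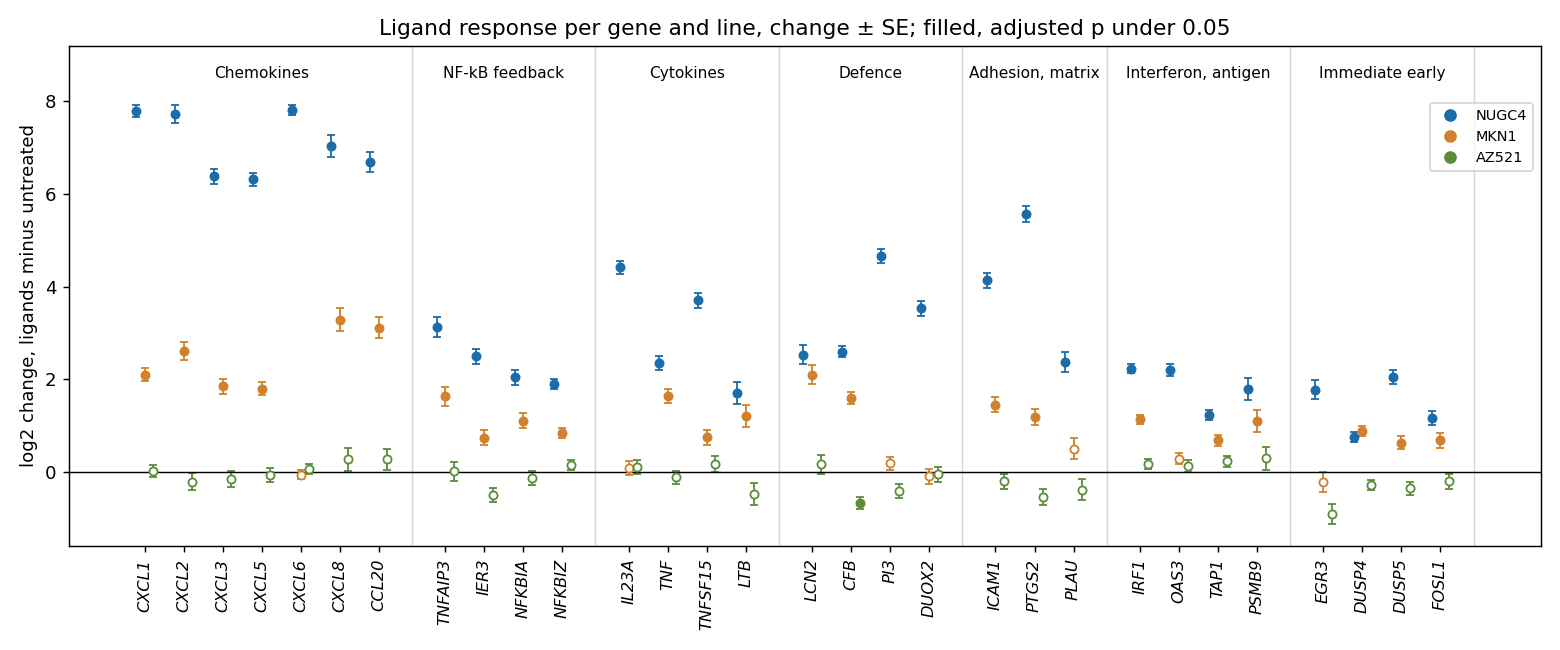
Log2 change, ligands minus untreated, for genes of the fixed lists in each line, with bars for the SE; filled points passed an adjusted p of 0.05. The chemokine genes shown rose by 6.32 to 7.82 in NUGC4, and in AZ521 none of the 13 tested passed.

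Altogether 5579 of 11422 genes passed in NUGC4, 1993 up and 3586 down, and 558 of them changed by at least 1 on the log2 scale, 329 up and 229 down. Of 15 response lists 11 were called, all up, and 9 of these held with an estimated correlation. Other splits of the same NUGC4 arrays called 6 to 12 lists with the preset correlation, so the number of lists does not set the real grouping apart. Adjusted over the list alone, every list but the cell cycle list had the counts given above. The share of rises was 35.7%, but 53.1% after each array was centred on the median of the tested genes (2835 up, 2500 down), a centring that by its construction moves rises and falls towards balance; median centring left 3299 falls and quantile normalization 3341. The GAPDH 3' minus 5' probe set difference, a sign of RNA quality, was higher on the ligand arrays of NUGC4 by 0.105 ± 0.032 (SE).

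In MKN1 the response was smaller and held chemokine and NF-kB genes. CXCL8 rose by 3.29 ± 0.24 (SE, n = 3 per group), CCL20 by 3.12 ± 0.22, CXCL2 by 2.61 ± 0.19 and CXCL1 by 2.10 ± 0.13. Untreated values were 2.80 to 3.59 for CXCL8, 2.66 to 3.07 for CCL20 and 3.81 to 3.88 for CXCL1. These lie near background, which makes the sizes of the 3 rises imprecise. LCN2, a secreted protein that binds bacterial iron carriers, rose by 2.10 ± 0.21, and the transcription factors MAFF and CEBPD rose by 2.07 ± 0.12 and 1.77 ± 0.09. No fall reached 1: MAP2K6, a kinase that activates p38, fell by 0.99 ± 0.13 and RETREG1, a receptor for autophagy of the endoplasmic reticulum, fell by 0.77 ± 0.11.

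Of 13 NF-kB feedback genes 9 rose in MKN1, and 11 when adjusted over the list alone, with TNFAIP3 up by 1.63 ± 0.21 and NFKBIA by 1.11 ± 0.16. Of 13 chemokine genes 6 rose by either adjustment. Of 12 cytokine genes 3 rose (6 when adjusted over the list alone), among them TNF by 1.64 ± 0.15. Of 13 apoptosis inhibitors 6 rose (8 when adjusted over the list alone), among them SOD2, the mitochondrial superoxide dismutase, by 1.13 ± 0.13. Of 13 antigen presentation genes 4 rose (6 over the list alone), TAP1 by 0.68 ± 0.11. Of 10 defence genes 2 rose (4 over the list alone), and of 13 matrix and adhesion genes 2 rose (5 over the list alone), namely ICAM1 by 1.45 ± 0.16 and PTGS2 by 1.18 ± 0.17. CFB, complement factor B, was the other defence gene, with a rise of 1.59 ± 0.13.

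Of 19 immediate early genes 4 rose in MKN1 (7 up and 1 down over the list alone), DUSP4, an ERK phosphatase, by 0.88 ± 0.11 and MYC by 0.58 ± 0.10. That list's call was lost with an estimated correlation (adjusted p = 0.198 with an estimated correlation). Of 13 MyD88 signalling genes only IRAK2 rose, by 1.24 ± 0.09. Of 22 interferon response genes 2 rose, IRF1 by 1.14 ± 0.10 and the RNA sensor gene RIGI by 0.85 ± 0.11, and the list missed the threshold (adjusted p = 0.0501) with a median of 0.00. No gene of the EGFR ligand, cell cycle, cholesterol, stress response, hypoxia and housekeeping lists passed in limma; at an unadjusted p under 0.05 there were 0, 1, 0, 3, 4 and 0. TLR2 had a change of 0.11 ± 0.12, which did not pass. Adjusted over the list alone, 2 stress response and 2 hypoxia genes fell. These lists, where tested, did not pass, with adjusted p of 0.153 for cell cycle, 0.415 for cholesterol, 0.137 for stress response, 0.875 for hypoxia and 0.694 for housekeeping. With the replicate number as a fixed block the cell cycle list was called down (adjusted p = 0.011).

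In all, 210 genes passed in MKN1, 153 up and 57 down, of which 32 changed by at least 1, all up. The GAPDH 3' minus 5' difference was higher on the MKN1 ligand arrays by 0.030 ± 0.012 (SE), and 213 genes passed with it as a covariate, which was added after the data were seen. Of 15 response lists 9 were called, all up, and 8 held with an estimated correlation. Other splits of the MKN1 arrays called 3 to 9 lists with the preset correlation. The gene count was 113 with limma on the MKN1 arrays alone, 387 with the replicate number as a random block and 577 with array weights. TNFAIP3 and TAP1 lost their calls with the MKN1 arrays alone.

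In AZ521 few genes passed, and the chemokine and NF-kB genes were not among them. CXCL8 had a change of 0.27 ± 0.24 (SE, n = 3 per group) and CCL20 of 0.27 ± 0.22. TNFAIP3 had log2 values of 6.73, 6.79 and 6.63 with ligands and of 6.76, 6.69 and 6.66 untreated. In limma 0 of 13 chemokine and 0 of 13 NF-kB feedback genes passed (0 and 2 at an unadjusted p under 0.05). The largest rise was that of TFF1, by 1.14 ± 0.17 to 4.33 ± 0.18, a level below the filter. Rises at higher levels were those of LYSMD3 by 0.74 ± 0.09 and FAM117A by 0.94 ± 0.14. Falls at clear expression were those of TRIB1, a pseudokinase, by 0.83 ± 0.13, SGK1, a serum- and glucocorticoid-regulated kinase, by 0.75 ± 0.10, and PHLDA1 by 0.70 ± 0.10.

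The 6 gene lists of AZ521 that passed were called down relative to the other tested genes. Other splits of the AZ521 arrays called 1 to 5 lists. All 19 immediate early genes had changes below 0, with a median of -0.28, and the list was called down (adjusted p = 8.2e-14, and 0.0117 with an estimated correlation). No member passed over all genes, and 6 fell when adjusted over the list alone. EGR3, a growth-factor-induced transcription factor, had a change of -0.91 ± 0.21 and passed with the replicate number as a random block. FOSB had -0.85 ± 0.31 and passed with the number as a fixed block (adjusted p = 0.0331, with a range up to 0.736 over 16 alternatives). The defence list was called down with 1 of 10 genes falling, and 3 over the list alone (adjusted p = 3.37e-05, and 0.0116 with an estimated correlation); CFB fell by 0.68 ± 0.13 from 3.61 ± 0.29, near background. The cytokine list was called down at an adjusted p of 0.0128, and 0.0441 with an estimated correlation, with 0 of 12 genes past the threshold (3 at an unadjusted p under 0.05) and 2 falling over the list alone; it was not called with fry, with the stricter filter on dim genes, or without ligand replicate 2 or untreated replicate 2.

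Calls for 3 more AZ521 lists were lost with an estimated correlation, apoptosis inhibitors (adjusted p = 0.0855 with an estimated correlation), matrix and adhesion (0.11) and hypoxia (0.076). The apoptosis inhibitors also lost theirs with the replicate number as a block (adjusted p = 0.0828, with a range of 0.0269 to 0.192 over 19 alternatives); over that list alone 1 gene rose and 2 fell. The 3 lists had median changes of -0.02, -0.11 and -0.06, with 6, 1 and 5 of 13 genes above 0. The median over all tested genes was 0.025. No member of these 3 lists passed over all genes, and none of the MyD88 signalling, EGFR ligand, interferon, antigen presentation, cell cycle, cholesterol, stress response and housekeeping genes did. The tested lists among these did not pass either, with adjusted p of 0.13 for MyD88 signalling, 0.694 for interferon, 0.311 for antigen presentation, 0.875 for cell cycle, 0.181 for cholesterol, 0.982 for stress response and 0.975 for housekeeping. NF-kB feedback (0.071) and chemokines (0.418) did not pass. The NF-kB feedback list was called down with quantile normalization, the mean of all probe sets and array weights, and without ligand replicate 1, ligand replicate 2 or untreated replicate 3; over 19 alternatives its adjusted p ranged from 0.00347 to 0.529. Among identity genes 1 of 10 gastric genes rose, TFF1, and 2 of 12 epithelial genes fell, CLDN4 by 0.57 ± 0.08 from 3.77 ± 0.07 and CLDN7 by 0.97 ± 0.20 from 5.4 ± 0.53 (adjusted p = 0.0497, with equal values on 1 array of each group); both encode tight junction claudins, and CLDN7, which was singled out after its values were seen, lost its call in 10 of 17 alternatives.

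**Figure D3:**
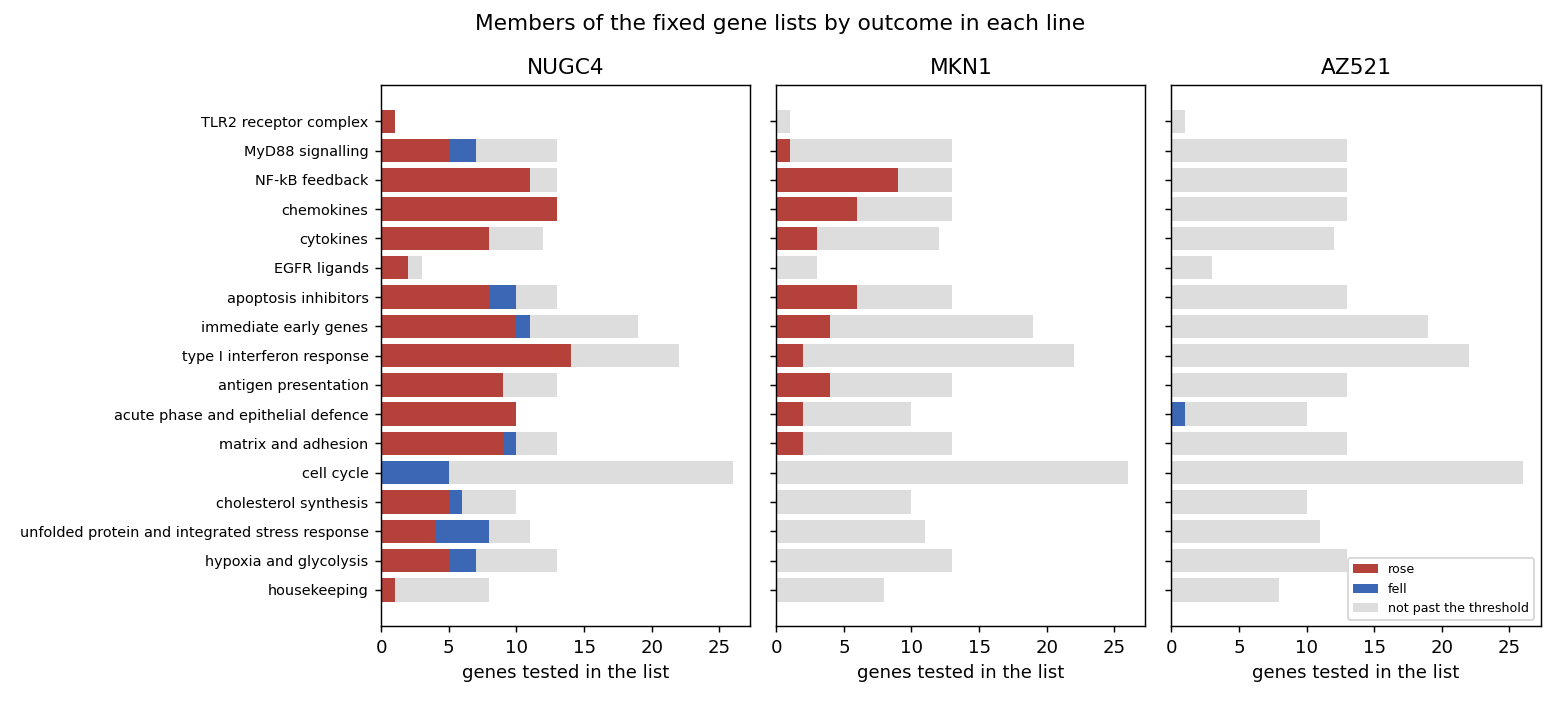
Number of tested genes in each fixed response list that rose, fell or did not pass the threshold in each line (adjusted p of 0.05 over all genes tested). Chemokine genes rose in 13 of 13 cases in NUGC4, 6 of 13 in MKN1 and 0 of 13 in AZ521.

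Altogether 36 genes passed in AZ521, 25 up and 11 down, of which 1 changed by at least 1. The share of rises was 69.4%, but 56.2% after median centring and 50% after centring on the tested genes. The count rests on the shared estimate of spread: limma on the AZ521 arrays alone called 0 genes, with 1192 at an unadjusted p under 0.05. It was 17 with the mean of all probe sets, 109 with array weights and 139 with the replicate number as a random block, and 18 without ligand replicate 2 and 22 without untreated replicate 1. TRIB1 lost its call in 2 and CFB in 4 of 6 fits that left out 1 array, and PHLDA1 and CLDN4 lost theirs with the mean of all probe sets. With the number as a fixed block, PRSS21, NUDT16L2P and FBXO11 lost their calls (adjusted p = 0.066, 0.0672 and 0.0892; highest over 17 alternatives 0.261, 0.414 and 0.524).

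NUGC4 and MKN1 shared 117 rises and 25 falls, where independent lists of these sizes would share 26.7 and 17.9, and 16 genes moved in opposite directions. The lines have no control arrays in common, but both tests of a gene use its 1 spread estimated over all 18 arrays. The 2 sets of calls are therefore not independent, and the numbers for independent lists are only a guide. Among the 117 shared rises the median change was 1.13 in NUGC4 and 0.65 in MKN1, and 92 were larger in NUGC4. The same 117 genes had a median of -0.07 in AZ521, where 72 were below 0, 0 passed as rises (7 at an unadjusted p under 0.05) and 2 passed as falls (20). NUGC4 and AZ521 shared 5 calls with the same sign and 20 with opposite signs, and MKN1 and AZ521 shared 0 and 4. Changes correlated across genes, which are not independent replicates, at 0.39 for NUGC4 with MKN1, -0.21 for NUGC4 with AZ521 and -0.15 for MKN1 with AZ521.

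The test of the difference itself placed the chemokine response of NUGC4 above that of both other lines. The response of CXCL6 was larger in NUGC4 than in MKN1 by 7.88 ± 0.14 (SE, n = 3 per group), that of CXCL1 by 5.69 ± 0.19, and that of SERPINB7 by 5.66 ± 0.17. XDH, the purine-degrading enzyme xanthine dehydrogenase, differed by 4.78 ± 0.22, and PI3 by 4.48 ± 0.21. Of 13 chemokine genes 13 rose more in NUGC4 than in MKN1, as did 8 of 10 defence genes and 11 of 22 interferon response genes. Against AZ521 the NUGC4 response was larger by 7.94 ± 0.27 for CXCL2, 6.77 ± 0.34 for CXCL8, 6.43 ± 0.31 for CCL20 and 6.11 ± 0.24 for PTGS2. CXCL1 in MKN1, and CXCL8 and CCL20 in AZ521, started near background, so the sizes of these differences are imprecise.

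MKN1 exceeded AZ521 in the response of CXCL8 by 3.02 ± 0.34, of CCL20 by 2.85 ± 0.31, of PHLDA1 by 2.41 ± 0.14, of MAFF by 2.37 ± 0.17 and of CFB by 2.27 ± 0.18. For CXCL8 and CCL20 both lines started near background, which makes the sizes imprecise. Set tests of the response differences between lines, added after the data were seen, put the chemokine list higher in NUGC4 than in MKN1 (median difference 3.75, adjusted p = 3.43e-05 with an estimated correlation) and higher in MKN1 than in AZ521 (median difference 0.25, adjusted p = 0.000375 with an estimated correlation). The NF-kB feedback list was higher in MKN1 than in AZ521 (adjusted p = 0.00308 with an estimated correlation), while its difference between NUGC4 and MKN1 did not pass with an estimated correlation (adjusted p = 0.0601). The immediate early list was higher in MKN1 than in AZ521 by a median of 0.49 (adjusted p = 0.0181 with an estimated correlation).

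**Figure D4:**
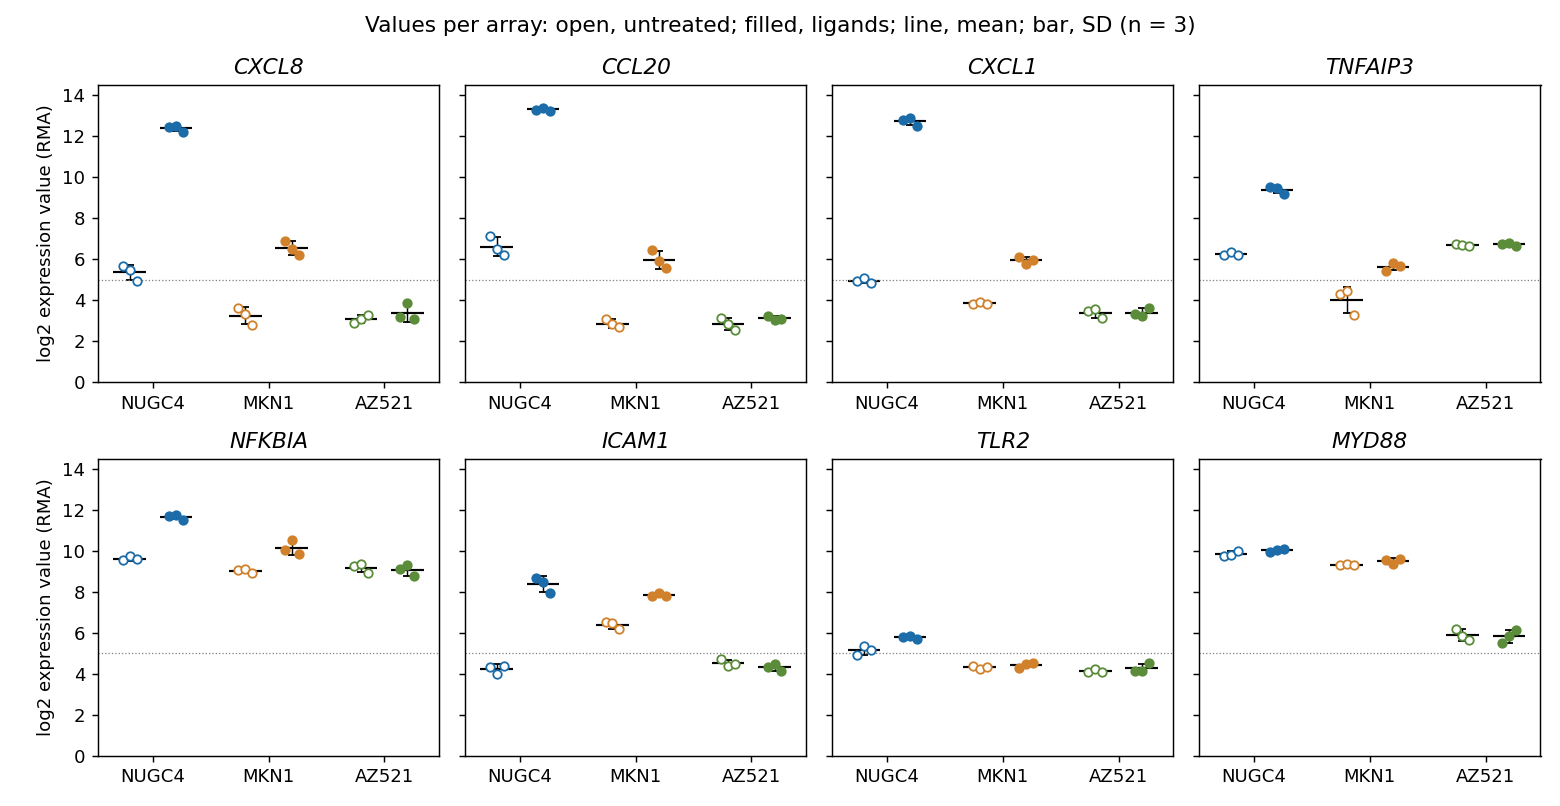
Log2 expression values of 8 genes on every array, untreated (open) and with ligands (filled), with the mean and SD of 3 arrays; the dotted line marks the log2 value of 5 used as the filter. CXCL8 reached 12.40 in NUGC4, 6.52 in MKN1 and 3.35 in AZ521 with ligands.

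The response differed in 3375 genes between NUGC4 and MKN1 (1283 higher and 2092 lower), in 4531 between NUGC4 and AZ521 (1531 and 3000), and in 227 between MKN1 and AZ521 (117 and 110). The share of higher calls was 38.0%, 33.8% and 51.5%, but 53.5%, 56.3% and 71.8% after centring on the tested genes, and for MKN1 minus AZ521 also 62.0% after median centring and 63.9% after quantile normalization. The MKN1 minus AZ521 count was 418 with a random block and 485 with array weights, and 147 without AZ521 untreated replicate 1 and 144 without MKN1 untreated replicate 2. CXCL1, CXCL2 and CXCL3 have similar sequences, so their probe sets may share signal.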

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

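The tests of RNA quality, of scaling with the spike-ins, of exchanged labels, and of a hybridisation batch or a mixed culture behind the AZ521 levels were chosen after the values were seen, as were the regroupings that part the replicate pairs. A pair of tests of a handling effect common to the lines, on the immediate early list between MKN1 and AZ521 (adjusted p = 0.0181) and on the 16 of 36 genes changed in AZ521 with the same sign in MKN1, were set aside after their results were seen, because a ligand response in MKN1 on top of such an effect would give the same values.

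Responses that differed between lines in a test of the difference numbered 3375 genes for NUGC4 minus MKN1, 4531 for NUGC4 minus AZ521 and 227 for MKN1 minus AZ521. The 10 largest for NUGC4 minus MKN1, on the log2 scale, were CXCL6 (7.88), CXCL1 (5.69), COXFA4L3 (5.66), SERPINB7 (5.66), CXCL2 (5.12), XDH (4.78), SPRR2B (4.65), CXCL3 (4.54), CXCL5 (4.53) and PI3 (4.48). Those for NUGC4 minus AZ521 were CXCL2 (7.94), CXCL1 (7.77), CXCL6 (7.76), CXCL8 (6.77), CXCL3 (6.54), CCL20 (6.43), CXCL5 (6.39), COXFA4L3 (6.12), PTGS2 (6.11) and SERPINB7 (5.87). Those for MKN1 minus AZ521 were CXCL8 (3.02), CCL20 (2.85), CXCL2 (2.82), PHLDA1 (2.41), MAFF (2.37), CFB (2.27), CXCL1 (2.08), CXCL3 (2.01), LCN2 (1.94) and CXCL5 (1.86). Among 2907 probe sets without a single gene name, which the comparisons did not use, 1077 passed in NUGC4, 22 in MKN1 and 2 in AZ521.

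The first pattern is the number of genes changed in NUGC4, 5579, with 3586 falls. With the GAPDH 3' minus 5' difference of each array as a covariate 4679 genes passed. That exceeds the bound of 3719 by more than 443, the spread between the highest and lowest counts of fits that left out 1 array. An effect of this measure that is linear, with the same slope in all lines, is argued against as the whole cause. RNA quality itself stays open, because the slope comes only from differences within groups. In NUGC4 the measure parted the groups without overlap, at 0.528 to 0.617 with ligands and 0.426 to 0.475 untreated. Scaling as the source of the falls of at least 1 is argued against for the 65 of 229 such genes that lie at the levels of the hybridisation spike-ins, since these, which enter each array in a fixed amount, did not fall as far (lowest 95% limit of the change of any of the 3 spike-ins -0.43). It stays open for the excess of small falls, because the spike-ins changed by -0.079 on average (95% interval -0.32 to 0.16), a range that includes both 0 and the median change of the tested genes, -0.08. A response of the cells to the ligands, which the design names, remains an open explanation.

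The second pattern is that genes which rose in both other lines leaned downwards in AZ521, with 72 of 117 below 0. Exchanged ligand and untreated labels in AZ521 cannot be told apart from a line with little response, because 2 of the 117 passed as falls and 0 as rises. A weak response of AZ521 to the ligands, and a handling effect common to the lines, stay open.

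The third pattern is the distance of AZ521 from the other lines before any ligand. A hybridisation batch of the size the spike-ins show is argued against, as the epithelial genes were lower by a median of 6.36 than in MKN1 while the largest spike-in difference between lines was 2.43. A batch with larger effects on these genes cannot be told apart from the line, since bioB was low on all 6 AZ521 arrays. A culture made largely of epithelial cells like the other lines, with mesenchymal cells mixed in, is argued against. Only 1 of 12 epithelial genes lay within 2 on the log2 scale of the lower of the other lines. A small share of epithelial cells could lie below that margin too, so it stays open. Both comparisons use the epithelial values that made the pattern, so neither is separate support for a difference between the lines. A difference between the lines themselves, which the design names, stays among the open explanations. The origin of the line stays open: stocks of AZ521 have been listed elsewhere as a duodenal adenocarcinoma line, which was not tested here.

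Other groupings of the same arrays were refitted. For the responses and the untreated differences the 6 arrays make 10 splits, too few for a share under 0.05. The real split was the only 1 with as many genes: 5579 in NUGC4, 210 in MKN1 and 36 in AZ521 against 3, 3 and 9 at most in the others, and 9058, 9529 and 9195 between untreated lines against 0, 0 and 0. Among the other splits that part as many pairs, the highest counts were 0 in NUGC4 and 1 in AZ521. For the number of lists called, 4 of the 10 splits gave as many as the 11 in NUGC4 (highest other 12), 2 as many as the 9 in MKN1 (highest other 9) and 1 as many as the 6 in AZ521 (highest other 5). The lowest other counts were 6, 3 and 1 lists. The number of lists called therefore does not set the real grouping apart in NUGC4 or MKN1. Every other split holds unequal numbers of ligand and untreated arrays on each side, so part of a response can remain in it.

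For response differences 100 regroupings within the lines were drawn, the real one included. For NUGC4 minus MKN1, 11 of 100 gave as many as 3375 genes, with 4471 the highest other, so chance was not excluded by this count. All 11 kept the real grouping of NUGC4, and the highest without it was 8; the 4471 came from exchanging the labels of MKN1 alone. For NUGC4 minus AZ521 only the real grouping, 1 of 100, gave as many as 4531 (highest other 4242). For MKN1 minus AZ521 1 of 100 gave as many as 227 (highest other 145). For genes changed the same way in NUGC4 and MKN1 1 of 100 gave as many as 142 (highest other 16). These shares do not exclude chance for the differences or the sharing themselves, because regrouping within the lines also removes the response of each line. The counts rest mostly on the grouping of the first line named, since without its real grouping the highest were 3, 4 and 0. Of the 100 draws only 13, 9 and 11 kept that grouping, the real one included, too few for a share under 0.05. Among the regroupings that part all replicate pairs of NUGC4 and AZ521, 1 of 32 gave as many for NUGC4 minus AZ521 (highest other 3986), 1 of 80 for MKN1 minus AZ521 (113) and 1 of 80 for the shared genes (16), but 18 of 80 for NUGC4 minus MKN1 (4471).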

How the results depend on the processing

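Centring on the tested genes and the GAPDH covariate were chosen after the data were seen; the other alternatives were not. Most results kept their direction and their side of the threshold, and for each change below the cause was not tested unless fewer arrays or a stricter threshold give it. Values near background limit the dim genes, so folds that start from log2 values of 2 to 4 are imprecise. A sign change was counted as reversed only for a value past the threshold in either setting, which leaves 141 sign changes of values past it in neither. Of 474 named values 388 changed neither side nor sign in any setting, where those 141 sign changes were not counted as changes.

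Requiring a change of at least 1 left 558 genes in NUGC4, 32 in MKN1 and 1 in AZ521, 470, 726 and 46 for NUGC4 minus MKN1, NUGC4 minus AZ521 and MKN1 minus AZ521, untreated differences of 3817, 4486 and 3700, and 28 shared changes. An adjusted p under 0.01 left 107 in MKN1, 11 in AZ521, 1986 for NUGC4 minus MKN1, 75 for MKN1 minus AZ521 and 75 shared. Array weights gave 577 in MKN1, 109 in AZ521, 485 for MKN1 minus AZ521 and 328 shared. With only the lines compared in the fit, 113 passed in MKN1, 0 in AZ521 (limma, 1192 at an unadjusted p under 0.05) and 83 shared. The mean of all probe sets gave 17 in AZ521. In AZ521, 3 lists were called with an estimated correlation and 3 with fry, against 6. MyD88 signalling in MKN1 lost its call with no filter and without either of 2 arrays, and the interferon list there gained one in 4 settings and without any of 3 arrays.

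Reversed values were ATXN1 in AZ521, -0.08 without probe sets of the x and s kinds (adjusted p 0.946, range 0.00412 to 0.946 over 17 alternatives), and ELF3 between untreated NUGC4 and MKN1, 0.39 with the mean of all probe sets (adjusted p 0.005, range 0.005 to 0.995 over 15).

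With the replicate number as a fixed block 5903, 283 and 49 genes passed in NUGC4, MKN1 and AZ521, and 3809, 4950 and 279 in the differences; as a random block (correlation 0.197) 387 passed in MKN1, 139 in AZ521, 418 for MKN1 minus AZ521 and 244 shared. In MKN1 the arrays share only a number (correlations of 0.11, 0.06 and 0.04), and 2 of 3 ligand arrays correlated best with their own. There the fixed block ended the call of SLC2A10 (adjusted p 0.0574, range 0.00557 to 0.191) and added DDIT3 (0.0337, range 0.0108 to 0.232) and the cell cycle list (0.011, range 0.00357 to 0.972). Besides these and the calls given with the results, the fixed block changed no other call among the named genes and lists. The random block added the calls of DDIT3, SLC2A1 and XBP1 in MKN1 and of EGR3 in AZ521, and ended none.

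Leaving out 1 array gave 4815 to 5258 genes in NUGC4, 146 to 197 in MKN1, 18 to 35 in AZ521, 2857 to 3366, 4057 to 4479 and 144 to 232 in the differences, 8776 to 8874, 9279 to 9337 and 8866 to 8911 between untreated lines, 11 to 12, 9 to 11 and 5 to 6 lists, and 96 to 141 shared. AZ521 fell to 18 without ligand replicate 2 and 22 without untreated replicate 1, and MKN1 minus AZ521 to 147 without AZ521 untreated replicate 1 and 144 without MKN1 untreated replicate 2.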

Other observations

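The lists of nucleolar and cilium genes below were written after a scan of gene families had been seen, but before they were tested.

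NUGC4 cells also changed genes outside the lists above. A scan of 196 families of gene symbols with at least 8 members, in 588 tests, passed the threshold only for the CXCL family, in NUGC4 (9 of 9 genes rose, adjusted p = 0.00323 with an estimated correlation) and in MKN1 (5 of 9 rose, adjusted p = 0.00323). Families of ribosome biogenesis leaned upwards in NUGC4 without passing, with 7 of 8 RRP genes rising (adjusted p = 0.461) and 9 of 10 UTP genes (adjusted p = 0.688).

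A hypothesis was that ribosome biogenesis genes at large shifted up in NUGC4, and a separate list of nucleolar genes, which make and assemble ribosomes, was tested. Of 32 tested, 22 rose and 2 fell in NUGC4, with a median of 0.32 (adjusted p = 0.0211 with an estimated correlation), in line with the hypothesis, which was found on the same data. In MKN1 the list was called up with a median of 0.11 (adjusted p = 0.0192), and in AZ521 down with a median of -0.09 (adjusted p = 0.0211), where 0 single genes passed in limma.

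A further hypothesis was that primary cilium genes shifted down in NUGC4, where 11 of 17 IFT genes fell and 2 rose without the family passing (adjusted p = 0.95) and CYS1 and BBS12 were among the largest falls. Of 25 genes of a separate cilium list 15 fell and 0 rose, with a median of -0.42, but the list did not pass with an estimated correlation (adjusted p = 0.115; 0.00013 with the preset correlation), so the test leaves it open.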
